A study of Mus musculus with 18 samples.

How the data were processed

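Polyadenylated RNA from 18 samples of neonatal mouse cardiac fibroblasts was sequenced with a stranded mRNA library kit, per the labels' protocols. The submitters' processing notes name fastp for trimming, HISAT2 for alignment and HTSeq for counting, without versions, and the mouse build mm39. They do not state whether counting used strand, so reads of overlapping and antisense genes could not be told apart. The deposited table gives FPKM per gene symbol. The annotation was not given in the sources used here, and the reference at hand was of another build, so no coordinates are given. Groups and replicate numbers were taken from the sample labels, and each column of the table was matched to a sample by its name.

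The table held 21878 genes, 4137 of them at 0 in every library. Symbols are printed as the table gives them, including older ones such as Ctgf, Cyr61 and Ddx58. Some symbols had been turned into dates: 27 rows had date names, holding at most 0.294% of a library's reads, and 4 rows had repeated names, and none of these is named in the text. The FPKM values of a gene are whole multiples of the value of 1 read, which allowed the reads behind them to be recovered. All libraries were whole within 0.01 read in 100% of rows, and the recovered reads made up at least 99.9995% of totals that ran from 14.08 to 21.11 megareads per library. On simulated tables of 17434 rows, the recovery returned 99.9% of rows exactly. FPKM sums ran from 352005 to 373678 per library. The 10 most-read genes of a library took 6.13 ± 0.17% of reads in si-NC, 7.71 ± 0.21% in Ang-II, 5.38 ± 0.13% in OE-NC and 5.94 ± 0.1% in OE-TEAD1. Replicates were compared over genes with at least 300 reads, and the chi-square per gene was 2.87 to 10.94 in the 18 replicate pairs, so no pair differed by as little as sampling noise.

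Genes with at least 1 FPKM in at least 3 of the 18 libraries were tested, 11844 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a pseudocount of 1, a mean for each of the 6 groups over all 18 libraries (12 residual degrees of freedom, 17.31 with the prior), and eBayes with a trend. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison, and genes were called at an adjusted p under 0.05. The comparisons were si-TEAD1 with si-NC, Ang-II with si-NC, si-TEAD1+Ang-II with Ang-II, OE-TEAD1 with OE-NC, the interaction of knockdown and angiotensin II, and OE-NC with si-NC. These, the gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined.

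The test was run on simulated negative binomial reads made from the real genes' means, with 200 genes changed. The dispersion of 0.01 was assumed, so the shares called hold for that spread and not for noisier genes. They also hold only for few changed genes, and the real comparisons called far more than were changed here. In the simulated si-TEAD1 comparison (11468 genes tested) the test called 82.4% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 7.2% of calls were unchanged genes. For Ang-II (11464 genes) it called 74.2%, 100% and 100%, with 2.2% of calls unchanged. For si-TEAD1+Ang-II (11051 genes) it called 79.7%, 98.4% and 100%, with 3.7% unchanged, and for OE-TEAD1 (11717 genes) 75%, 100% and 100%, with 5.3% unchanged.

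Of 34 gene lists, 31 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. camera was also run with an estimated correlation. Members called over all genes are counted beside those called when adjusted over the list alone, which is given where it differs. The lists of 13 mitochondrially encoded genes (0 matched in the table), 7 erythroid genes (0 tested) and 8 neural crest and Schwann genes (1 tested) were not tested. Comparisons of fold changes across genes give the overlap of calls beside n1 × n2 / N for independent lists, and, where libraries were shared, the correlation and covariance of 100 simulated pairs of unchanged groups.

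Named genes were Tead1, Wnt4 and Brd4, the 10 rising and 10 falling called genes with the largest change, and up to 4 members of each list with the smallest adjusted p. Large changes had to reach a mean of at least 5 FPKM in the higher group, have groups that do not overlap, and have an ordinary gene symbol. In the interaction, where overlap of groups is not defined, that condition was left out. The list members printed were selected from those the rule names after their values were seen, and genes outside the rule are said to have been chosen then.

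The alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, eBayes without a trend, the compared groups alone in the fit, median-of-ratios and quantile scaling, a minimum fold of 2, the replicate number as a block, an estimated correlation for the lists, and leaving out each replicate in turn. Voom on the recovered reads with total or median-of-ratios library sizes, the lists under other scalings, the interaction lists with a pseudocount of 0.1, a split of shared groups into 1 and 2 libraries for the comparisons across genes, and thinning of all libraries to the smallest total were added after seeing the data.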

Results

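Messenger RNA was sequenced from neonatal mouse cardiac fibroblasts, the matrix-producing cells of the heart wall, to follow what the transcription factor TEAD1 does in cardiac remodeling. The 18 libraries formed 6 groups of 3. In the siRNA arm, cells received a negative control siRNA (si-NC) or an siRNA against Tead1 (si-TEAD1), were stimulated with angiotensin II (Ang-II), or had both the knockdown and the stimulus (si-TEAD1+Ang-II). In the overexpression arm, cells carried a negative control (OE-NC) or overexpressed TEAD1 (OE-TEAD1). The labels give no dose or duration of angiotensin II and do not say whether the Ang-II cells also received the control siRNA. If these cells did not, an effect of transfection cannot be told apart in any comparison that uses the Ang-II group. The labels also do not say that replicates were separate cultures, so p-values measure only the spread between these libraries.

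Values are FPKM (fragments per kilobase of gene, scaled to library size), given as mean ± SD with n = 3. Library totals recovered from these values, in megareads (M), were 20.41 to 20.65 for si-NC, 19.26 to 20.26 for si-TEAD1, 19.21 to 21.11 for Ang-II and 19.23 to 21.03 for si-TEAD1+Ang-II. In the same unit OE-TEAD1 libraries held 19.33 to 19.76 and OE-NC libraries 14.08 to 14.75. Between 15184 and 15789 genes had a value above 0 in a library. Markers of other cell types were abundant in every group. Group means of Tnnt2, the most abundant cardiomyocyte marker, were 1258 to 1896 FPKM, and those of the macrophage marker Lyz2 361 to 500. For the cell identity lists, regulation within a cell type and a change in cell shares therefore cannot be told apart. The same limit holds for other genes that cardiomyocytes express, such as Myh7 and those of the respiratory chain. Fold changes are differences of log2(FPKM + 1), which understate the change of genes near or below 1 FPKM, and gene p-values are from limma with Benjamini-Hochberg adjustment over 11844 genes. A gene is said to rise, fall or change only at an adjusted p under 0.05. The genes with the largest rises and falls named below had libraries that did not overlap between the compared groups.

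Tead1 itself followed the labels in every manipulated group. It was at 54.3 ± 1.91 FPKM in si-NC and fell to 19.9 ± 1.6 in si-TEAD1 (log2 fold change -1.41, SE 0.08, adjusted p = 1.05e-09). With angiotensin II it fell from 62.8 ± 0.852 to 20.2 ± 1.54 on knockdown (-1.59, SE 0.08, adjusted p = 9.12e-11). Overexpression raised it from 37.3 ± 1.45 to 116 ± 18 FPKM (1.60, SE 0.08, adjusted p = 1.13e-10), with the OE-TEAD1 libraries at 115, 99.2 and 135. Tead1 was slightly higher in Ang-II than in si-NC (0.21, SE 0.08, adjusted p = 0.0446). That call was lost when any of the 6 compared libraries was left out, with adjusted p up to 0.134, and when low genes were not filtered out (adjusted p = 0.079). The value depended on scaling: it was 0.33 (adjusted p = 0.00357) after median-of-ratios scaling, 0.26 (adjusted p = 0.0166) after quantile normalization and 0.34 (adjusted p = 0.000912) with voom on median-of-ratios library sizes. The OE-NC control had less Tead1 than si-NC (-0.53, adjusted p = 1.65e-05).

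Wnt4, the Wnt ligand of the series title, was a rare transcript that moved in the direction of Tead1 in each comparison with its own control. It was 1.66 ± 0.331 FPKM in si-NC, fell to 1.07 ± 0.156 with si-TEAD1 (-0.36, SE 0.12, adjusted p = 0.0188) and rose to 2.5 ± 0.459 with Ang-II (0.40, adjusted p = 0.00933). Knockdown under angiotensin II returned it to 1.61 ± 0.283 (-0.42, adjusted p = 0.00716), and the knockdown effect did not differ detectably with angiotensin II (difference -0.06, adjusted p = 0.893). OE-TEAD1 raised Wnt4 from 0.495 ± 0.114 to 0.97 ± 0.216 (0.39, adjusted p = 0.00803). Across the arms Wnt4 did not follow Tead1: OE-TEAD1 had more Tead1 than si-NC but a lower Wnt4 mean. Similarly, si-TEAD1+Ang-II had less Tead1 than si-NC at nearly the same Wnt4 mean. These values rested on 21 to 238 reads per library. The fall in si-TEAD1 lost its call without si-NC replicate 2 (-0.26, adjusted p = 0.109) or si-TEAD1 replicate 3 (-0.31, adjusted p = 0.0759). The rise in Ang-II lost it without Ang-II replicate 2 (0.29, adjusted p = 0.0628) or si-NC replicate 3 (0.32, adjusted p = 0.0526), and the fall under angiotensin II reached only adjusted p = 0.05 without Ang-II replicate 2 (-0.32).

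Brd4, which encodes the chromatin reader of the title, was not called with si-TEAD1, Ang-II, si-TEAD1+Ang-II or OE-TEAD1. Its level was 13.3 ± 0.239 FPKM in si-NC, 14.3 ± 0.266 in si-TEAD1 (0.10, adjusted p = 0.218), 12.2 ± 1.07 in Ang-II (-0.13, adjusted p = 0.0907) and 12.4 ± 0.967 in si-TEAD1+Ang-II (0.02 against Ang-II, adjusted p = 0.801). OE-NC had 15.4 ± 0.924 and OE-TEAD1 14.3 ± 0.277 (-0.10, adjusted p = 0.191). Its lower level with Ang-II was called without Ang-II replicate 3 (-0.19, adjusted p = 0.0167) and when the recovered reads were tested with voom (-0.14, adjusted p = 0.0478). Between the controls, Brd4 was called higher in OE-NC than in si-NC (0.19, adjusted p = 0.0089), a call lost after median-of-ratios scaling (0.13, adjusted p = 0.0537), after quantile normalization (0.13, adjusted p = 0.0503) and without OE-NC replicate 3 (0.15, adjusted p = 0.0555).

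**Figure D1:**
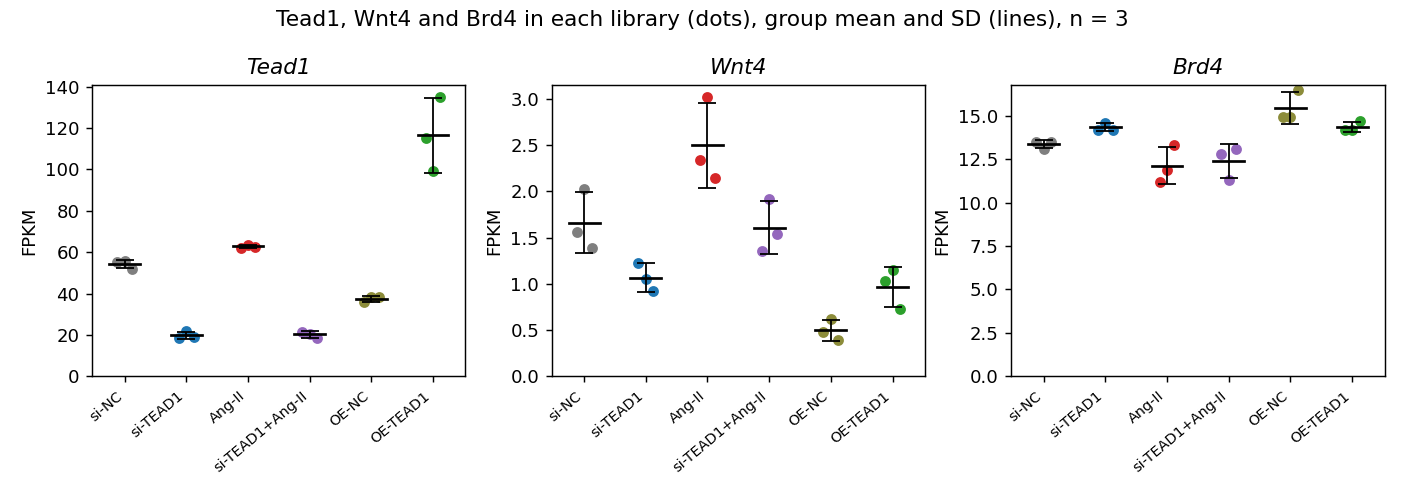
FPKM of Tead1, Wnt4 and Brd4 in the 6 groups, with a dot per library, a black line at the mean and bars of 1 SD. Tead1 averaged 19.9 and 20.2 FPKM in the knockdown groups and 116 in OE-TEAD1, while Brd4 means lay between 12.2 and 15.4.

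Across all genes the libraries separated by group. The first principal component carried 53.7% of the variance and ran from Ang-II (-34.4 to -34.1) and si-TEAD1+Ang-II (-31.2 to -29) through si-NC (-2 to 1.5), si-TEAD1 (7.9 to 10.4) and OE-TEAD1 (14.2 to 21.3) to OE-NC (37.7 to 38.6). The next components carried 18% and 16.4%.

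**Figure D2:**
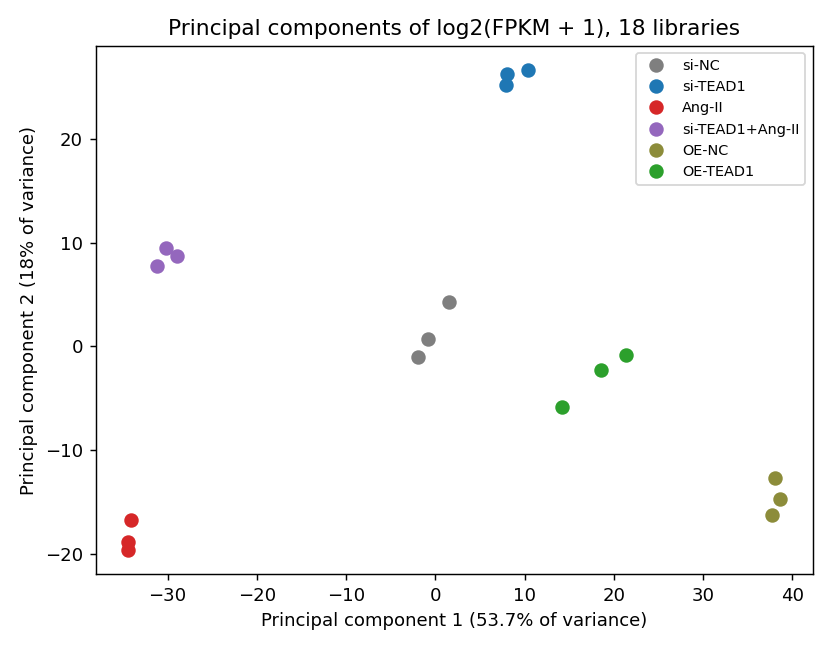
Scores of the 18 libraries on the first and second principal components of log2(FPKM + 1), colored by group, with a dot per library. The first component (53.7% of the variance) sets Ang-II near -34 and OE-NC near 38 at its ends.

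Knockdown of Tead1 in unstimulated fibroblasts, compared with si-NC, asked which transcripts depend on TEAD1 at rest. Most of the mitosis, S phase and interferon-response genes tested rose, and so did the chemokine genes Ccl2 and Ccl7. Among matrix genes, Postn and Tnc rose and Lox and Col11a1 fell. Igfbp3, a listed target of the YAP-TEAD complex, and the mesothelial gene Upk3b fell. The comparison called 5096 genes, 2435 higher and 2661 lower, and 232 of them changed at least 2-fold (159 higher, 73 lower). The larger direction turned with median-of-ratios scaling (2752 higher, 2264 lower).

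Every one of the 32 mitosis genes tested rose with si-TEAD1 (median log2 fold change 1.17, camera adjusted p = 2.23e-21, or adjusted p = 0.362 with an estimated correlation). Cdc20 rose from 11.7 ± 2.25 to 35.7 ± 2.88 FPKM (1.55, adjusted p = 1.12e-07), and Cenpe, Cenpf and Hmmr rose by 1.30, 1.23 and 1.17. Of 30 genes of DNA replication and S phase, 25 rose and 0 fell (26 and 0 adjusted over the list alone; median 0.44, adjusted p = 1.04e-08, or adjusted p = 0.362 with an estimated correlation), among them Pola1 (0.56) and Rfc2 (0.39). The cyclin gene Ccnd1 rose from 57.3 ± 6.24 to 172 ± 8.94 FPKM (1.57, adjusted p = 1.18e-08) and Myc by 0.68. Of the 32 interferon-response genes, 30 rose and 0 fell (median 1, adjusted p = 9.53e-13, or adjusted p = 0.362 with an estimated correlation). Oasl2 went from 4.83 ± 0.347 to 19.4 ± 2.68 FPKM (1.80, adjusted p = 7.37e-06), with Irf7 at 1.79, Psmb8 at 1.23 and Tap1 at 0.76. The chemokine genes Ccl2 (33.1 ± 10.7 to 236 ± 26.7 FPKM; 2.84, SE 0.27, adjusted p = 2.1e-07) and Ccl7 (7.81 ± 2.78 to 46.5 ± 4.38; 2.48, adjusted p = 1.73e-07) were among the 10 largest rises, which also held Tnfsf18, Gna14, Ptx3, Sprr1a, Ifit1, Tnc, Apln and Col15a1 (2.01 to 2.63). In the cytokine list 10 of 19 genes rose and 1 fell (11 and 1 adjusted over the list alone; median 0.59, adjusted p = 0.000335, or adjusted p = 0.362 with an estimated correlation), including Lif (0.59) and Cxcl12 (0.69).

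Among matrix genes, Postn rose from 490 ± 27 to 1211 ± 46.8 FPKM (1.30, adjusted p = 9.16e-11) and Tnc from 13.9 ± 1.28 to 63.7 ± 7.05 (2.11, adjusted p = 2.61e-11). Lox fell from 598 ± 32.6 to 236 ± 33.1 (-1.35, adjusted p = 1.88e-09) and Fbln5 by 0.82. Among collagens, 12 of 18 rose and 3 fell (median 0.22, adjusted p = 0.000816, or adjusted p = 0.362 with an estimated correlation). Col5a1 was up (0.78) and Col11a1 (-0.99) and Col8a1 (-0.77) were down. Contractile genes had 18 of 31 higher and 5 lower (18 and 7 adjusted over the list alone; median 0.21, adjusted p = 0.0173, or adjusted p = 0.423 with an estimated correlation), with Tpm1 (0.31) and Myh9 (0.39) up and Vcl (-0.37) and Fhl2 (-0.49) down. The surface and matrix genes Thy1 (12.6 ± 0.292 to 38.6 ± 2.29 FPKM; 1.54) and Dpt (113 ± 15.6 to 277 ± 16.1; 1.29) rose. Serpine1 rose from 50.2 ± 11.3 to 134 ± 7.48 (1.42) and Plau by 1.60.

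The largest fall after knockdown was Igfbp3, from 49.2 ± 1.85 to 7.91 ± 1.14 FPKM (-2.50, SE 0.12, adjusted p = 9.88e-11). Scel, Fgf18, Scg2, Dner, Kcne4, Gria4, Fst, Tbxa2r and Adamts9 followed (-2.28 to -1.66), and Kcne4 went from 134 ± 15 to 34.5 ± 3.42. Listed YAP-TEAD targets were not called as a list: 11 of 23 rose, among them Tgfb2 (0.82), F3 (1.14) and Fjx1 (0.83), and 8 fell (adjusted p = 0.27). Of 10 epicardial and mesothelial genes, 1 rose and 6 fell (median -0.34, adjusted p = 0.00382, or adjusted p = 0.362 with an estimated correlation), with Upk3b down from 48.8 ± 3.45 to 15.8 ± 2.29 and Msln by 1.16. Nuclear-encoded respiratory chain genes fell in 18 of 30 and rose in 0 (19 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.000899, or adjusted p = 0.362 with an estimated correlation). The list of p53 targets had 10 of 20 higher and 1 lower (median 0.18, adjusted p = 0.000273, or adjusted p = 0.362 with an estimated correlation), with Plk2 at 0.95 and Gdf15 at 1.14. NRF2 targets had 12 of 16 higher and 1 lower (median 0.26, adjusted p = 0.00592, or adjusted p = 0.421 with an estimated correlation), with Nqo1 up (0.63) and Gstm1 down from 315 ± 23.4 to 164 ± 9.33 FPKM (-0.94). All 10 list calls of this comparison used a preset correlation between genes, and none held with an estimated correlation.

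The other 21 lists were not called with si-TEAD1 (adjusted p from 0.0734 to 0.974). Components of the pathways in the series title were mixed: 0 of 4 Wnt ligands rose and 2 fell, 7 of 27 Wnt receptors and modulators rose and 14 fell (8 and 15 adjusted over the list alone), and 5 of 13 Wnt/beta-catenin targets rose and 3 fell. The ligands that fell were Wnt4 and Wnt5a (-0.25, adjusted p = 0.033). Wnt5a kept its call without si-TEAD1 replicate 3 and lost it without any other of the 6 libraries (-0.27 to -0.23, adjusted p from 0.0527 to 0.0976) or without the low-value filter (adjusted p = 0.055). Fzd1 and Fzd4 both fell by 0.62 and Ror2 rose by 0.55. BET proteins and P-TEFb had 1 of 11 higher and 2 lower (1 and 0 adjusted over the list alone, and 1 and 0 after median-of-ratios scaling). In the Hippo list 5 of 22 rose and 9 fell, with Dchs1 at 1.23 and Vgll3 at -0.91, and in the TEAD family Tead3 rose (0.23, adjusted p = 0.00569) as Tead1 fell. Other lists showed 17 higher and 10 lower of 34 matrix proteins (17 and 11 adjusted over the list alone), 9 and 6 of 22 matrix proteases, 12 and 8 of 29 TGF-beta signalling genes (12 and 9), 7 and 1 of 15 angiotensin and calcineurin genes (7 and 2), and 10 and 4 of 22 immediate early genes (11 and 4). Metabolic lists showed 9 higher and 2 lower of 23 cholesterol synthesis genes (9 and 3 adjusted over the list alone), 7 and 6 of 24 unfolded protein response genes (8 and 6; median 0.03, mean -0.01), 11 and 8 of 25 glycolysis genes, and 0 and 4 of 43 ribosomal protein genes (0 and 0). Cell identity lists showed 7 higher and 6 lower of 19 fibroblast genes (7 and 7 adjusted over the list alone), 1 and 8 of 21 cardiomyocyte genes, 4 and 1 of 7 pericyte genes, 0 and 4 of 19 macrophage genes (0 and 1), and 0 and 2 of 6 endothelial genes (median 0.11, mean -0.03).

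**Figure D3:**
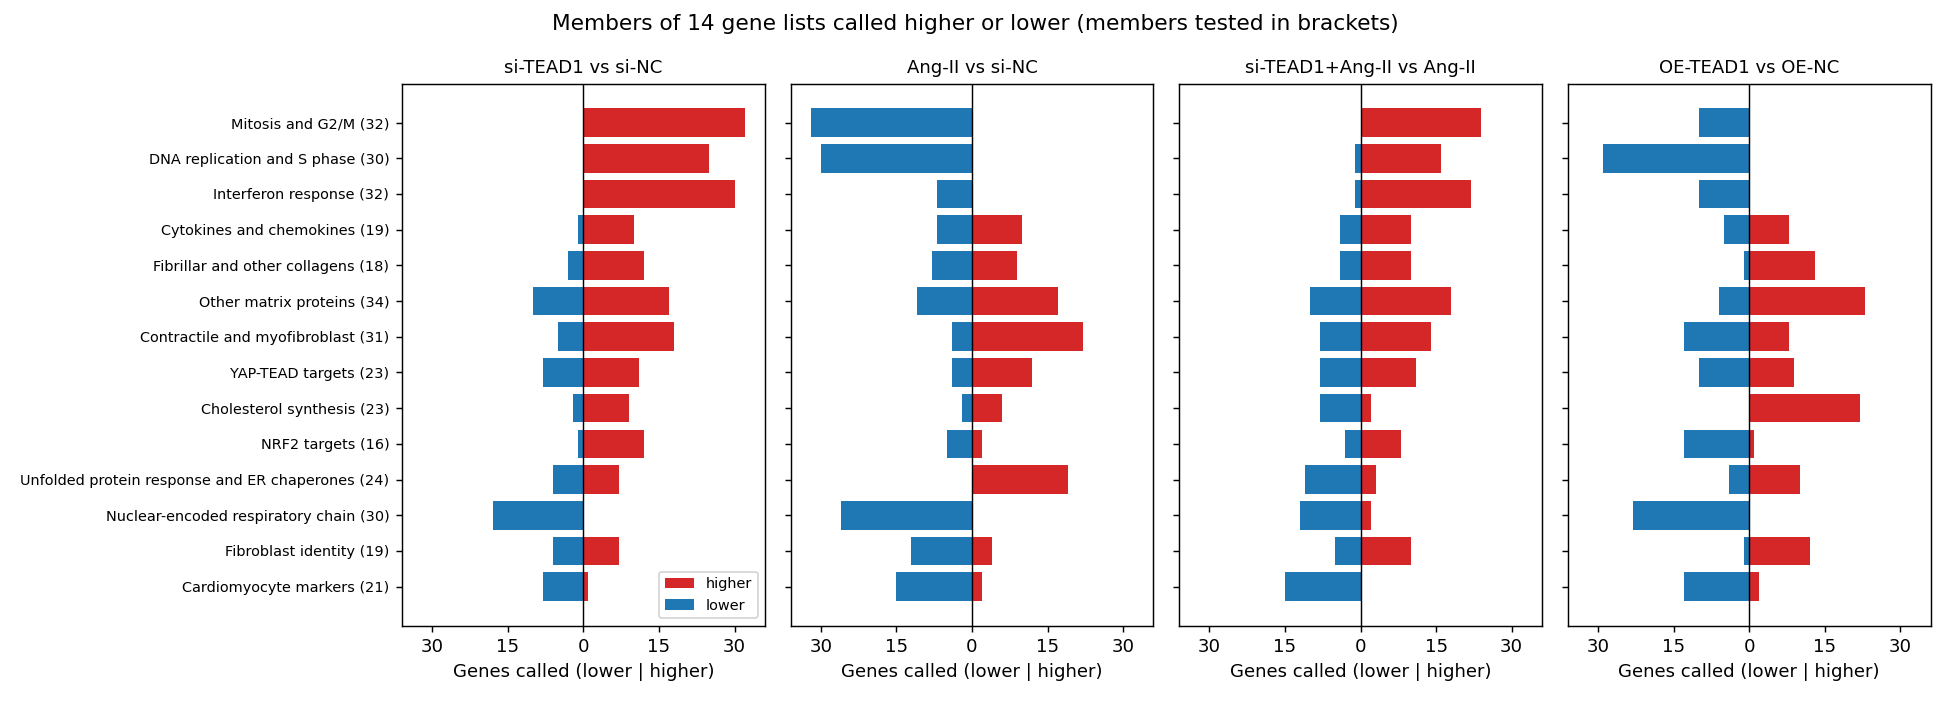
Number of called genes higher (right of 0) and lower (left of 0) in 14 gene lists for the 4 comparisons of the study. All 32 mitosis genes were higher with si-TEAD1 and all 32 were lower with Ang-II.

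Angiotensin II is a vasoactive peptide that drives cardiac fibrosis, and Ang-II against si-NC asked what it did to these fibroblasts. Most of the contractile genes tested rose, Acta2 among them, and so did Ctgf, Col1a1 and Serpine1. All the mitosis and S phase genes tested fell, and so did Ccnd1. Most of the unfolded protein response and chaperone genes tested rose. The cardiac fibroblast genes Pdgfra and Tcf21 fell.

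The comparison called 5706 genes, 1319 higher and 4387 lower (23.1% higher), with 80 rises and 337 falls of at least 2-fold. The split between directions depended on scaling, because the median gene lay at -0.102. Median-of-ratios scaling, which put the median at 0.006, gave 2584 higher and 2510 lower calls (50.7% higher), and quantile normalization, with a median of 0.024, gave 2584 and 2345 (52.4%). Changes of about 0.1 in the following therefore have no fixed direction relative to the other genes.

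Acta2, which encodes smooth muscle actin, rose from 580 ± 70.4 to 1372 ± 52 FPKM (1.25, SE 0.07, adjusted p = 1.79e-10). Contractile genes rose in 22 of 31 and fell in 4 (median 0.30, 0.4 above the median of all genes; camera adjusted p = 2.51e-13, or adjusted p = 0.0727 with an estimated correlation), with Csrp2 at 1.31, Tpm1 at 0.58 and Cald1 at 0.51. YAP-TEAD targets rose in 12 of 23 and fell in 4 (median 0.25, adjusted p = 2.81e-07), and this was the single list of the 6 comparisons whose call held with an estimated correlation (adjusted p = 0.0018). Ctgf went from 481 ± 22.8 to 1352 ± 39.7 FPKM (1.49, adjusted p = 3.06e-10) and Cyr61 from 94.3 ± 7.28 to 233 ± 13.1 (1.30, adjusted p = 9.84e-12), with Ccdc80 at 1.11 and Fjx1 at 0.94. The largest rise was Ltbp2, a matrix gene, from 9.51 ± 0.546 to 64.3 ± 4.3 (2.63, SE 0.07, adjusted p = 4.8e-14), ahead of Acan, Lurap1l, Mtnr1a, Megf6, Serpine1, Tnfrsf11b, Fstl3, Il6 and St14 (1.65 to 2.53). Serpine1 reached 198 ± 15 FPKM and Il6 9.31 ± 0.781.

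Of 18 collagen genes, 9 rose and 8 fell with angiotensin II (median 0.11, adjusted p = 0.00662, or adjusted p = 0.347 with an estimated correlation). Col1a1 rose from 657 ± 25.8 to 1179 ± 25.7 FPKM (0.84, adjusted p = 5.26e-11), Col5a2 from 353 ± 10.8 to 837 ± 39 (1.24) and Col11a1 from 77.2 ± 2.23 to 244 ± 2.74 (1.65). Col3a1, a gene chosen after its values were seen, fell from 990 ± 67.2 to 556 ± 22.2 (-0.83, adjusted p = 5.85e-09), and Col6a1 (-1.11) and Col6a2 (-1.22) fell too. Other matrix proteins rose in 17 of 34 and fell in 11 (18 and 11 adjusted over the list alone; median 0.16, mean -0.02, adjusted p = 0.000118, or adjusted p = 0.101 with an estimated correlation). Mfap4 (1.55) and Loxl2 (0.70) were up, and Dcn (433 ± 17.6 to 201 ± 6.2 FPKM; -1.10) and Fmod (-1.76) were down. TGF-beta signalling genes rose in 13 of 29 and fell in 9 (median 0.07, adjusted p = 0.00195, or adjusted p = 0.147 with an estimated correlation), with Pmepa1 up (0.89) and Id3 (-1.67) and Tgfbr2 (-0.86) down. The calls of collagens, matrix proteins and TGF-beta genes were lost with quantile normalization (adjusted p = 0.379, 0.298 and 0.109), and that of collagens also with median-of-ratios scaling (adjusted p = 0.0663).

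Ccnd1 fell from 57.3 ± 6.24 to 5.05 ± 0.932 FPKM (-3.27, SE 0.11, adjusted p = 5.11e-13), and Top2a from 16.9 ± 2.98 to 0.863 ± 0.124 (-3.26, adjusted p = 5.95e-12). All 32 mitosis genes fell (median -2.06, adjusted p = 1.56e-21, or adjusted p = 0.127 with an estimated correlation), including Mki67 (-2.59) and Cdk1 (-2.76), and all 30 genes of DNA replication and S phase fell (median -1.43, adjusted p = 5.85e-19, or adjusted p = 0.12 with an estimated correlation), including Mcm5 (-2.85) and Mcm6 (-1.76). Rrm2, Fam64a, Ube2c, Uhrf1, Abca8a and Prelp completed the 10 largest falls (-3.06 to -2.75), and Prelp went from 171 ± 11.8 to 24.5 ± 1.16. Pdgfra fell from 18.4 ± 2.27 to 4.24 ± 0.309 (-1.89) and Tcf21 from 334 ± 21.1 to 168 ± 12.6 (-0.99). Fibroblast identity genes fell in 12 of 19 and rose in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.101, but 0.0328 after median-of-ratios scaling and 0.00212 after quantile normalization).

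Unfolded protein response and chaperone genes rose in 19 of 24 and fell in 0 (20 and 0 adjusted over the list alone; median 0.26, adjusted p = 4.92e-14, or adjusted p = 0.0727 with an estimated correlation), with Hyou1 at 0.58, Hsp90b1 at 0.37, Canx at 0.37 and Pdia3 at 0.35. Of 4 Wnt ligands tested, 3 rose and 0 fell (median 0.51, adjusted p = 0.00857, or adjusted p = 0.13 with an estimated correlation, but 0.061 after median-of-ratios scaling): Wnt5a from 2.12 ± 0.0684 to 5.81 ± 0.632 FPKM (1.12, adjusted p = 1.74e-08), Wnt9a by 0.63 and Wnt4 as above. Cytokine genes rose in 10 of 19 and fell in 7 (11 and 7 adjusted over the list alone; median 0.32, adjusted p = 0.00292, or adjusted p = 0.347 with an estimated correlation, but 0.119 after median-of-ratios scaling and 0.107 after quantile normalization), with Cx3cl1 up (1.64) and Vcam1 down (-1.17). The angiotensin and calcineurin genes Nox4 and Rcan1 rose (0.98 and 0.51).

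Pericyte genes rose in 3 of 7 and fell in 3 (median 0.02, adjusted p = 0.0225, or adjusted p = 0.12 with an estimated correlation, but 0.137 after median-of-ratios scaling and 0.112 after quantile normalization), with Mcam (37.7 ± 4.99 to 113 ± 6.48 FPKM), Cspg4 and Rgs5 up. Glycolysis and hypoxia genes rose in 12 of 25 and fell in 4 (12 and 5 adjusted over the list alone; median 0.14, adjusted p = 0.000981, or adjusted p = 0.124 with an estimated correlation). P4ha1 (0.50), P4ha2 (0.75) and Eno1 (0.32) were up and Egln3 was down (-1.18). Cholesterol genes rose in 6 of 23 and fell in 2 (15 and 0 after median-of-ratios scaling; median 0.09, adjusted p = 0.000208, or adjusted p = 0.431 with an estimated correlation), and p53 targets rose in 8 of 20 and fell in 4 (9 and 4 adjusted over the list alone; median 0.12, adjusted p = 0.0061, or adjusted p = 0.407 with an estimated correlation, but 0.109 after quantile normalization). Respiratory chain genes fell in 26 of 30 and rose in 0 (28 and 0 adjusted over the list alone; median -0.21, adjusted p = 3.33e-05, or adjusted p = 0.159 with an estimated correlation), though 10 fell after median-of-ratios scaling. Cardiomyocyte genes fell in 15 of 21 and rose in 2 (16 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.00138, or adjusted p = 0.419 with an estimated correlation), with Tnni3 at -0.98 and Pln at -1.03.

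Of the 16 lists called with Ang-II, the estimated correlation left all but the YAP-TEAD targets uncalled. The 43 ribosomal protein genes had no fixed direction: 3 were higher and 7 lower as deposited (1 and 3 adjusted over the list alone), 18 and 0 after median-of-ratios scaling, and 0 and 15 after quantile normalization. In 8 uncalled lists (Hippo, Wnt receptors, Wnt/beta-catenin targets, angiotensin, immediate early, interferon, ribosomal and macrophage genes) the median was below 0 while camera gave an upward direction.

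Knockdown under angiotensin II, si-TEAD1+Ang-II against Ang-II, asked how much of the stimulated state depends on TEAD1. Ccnd1 and Tnc rose far above their stimulated levels, and 24 of 32 mitosis genes rose. Most of the interferon genes tested and Ccl2 rose. Lox, Col11a1, Wnt5a and Ctgf fell, while Acta2 and Col1a1 were not called.

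The comparison called 4957 genes, 2348 higher and 2609 lower, with 147 rises and 112 falls of at least 2-fold. Here too the larger direction turned with median-of-ratios scaling (2723 higher, 2309 lower). Tnc rose from 15.8 ± 1.49 to 215 ± 20.8 FPKM (3.69, SE 0.09, adjusted p = 1.83e-14) and Ccnd1 from 5.05 ± 0.932 to 57.7 ± 6.37 (3.28, SE 0.11, adjusted p = 9.71e-13), a level close to that of si-NC. Ccl2 rose from 11.6 ± 4.36 to 120 ± 14.5 (3.31, adjusted p = 2.01e-08) and Ngf from 10.8 ± 2 to 55.9 ± 1.96 (2.29). Tnfsf18, Gna14, Sprr1a, Ccl7, Tfpi2 and Notch4 were the other largest rises (2.10 to 3.29). Igfbp3 fell from 45 ± 5.41 to 7.4 ± 1.26 (-2.46, adjusted p = 5.37e-11) and Kcne4 from 169 ± 12.2 to 39.5 ± 4.94 (-2.07). Saa3, an acute-phase gene, fell from a variable 31.4 ± 11.9 to 0.31 ± 0.128 (-4.56, SE 0.92, adjusted p = 0.000621). Scg2, Cdo1, Ccl5, Fgf18, Dner, Adamts9 and Vnn1 were the remaining largest falls (-2.33 to -1.98).

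Among myofibroblast genes, of which this group of 6 was chosen after their values were seen, Acta2 was at 1396 ± 78.5 FPKM (0.02, adjusted p = 0.815; -0.11 after quantile normalization), Col1a1 at 1142 ± 61.2 (-0.05, adjusted p = 0.419) and Cyr61 at 244 (0.07, adjusted p = 0.374). Ctgf fell from 1352 ± 39.7 to 1035 ± 17.6 (-0.39, adjusted p = 0.00206). Serpine1 rose further, from 198 ± 15 to 415 ± 5.49 (1.07, adjusted p = 8.45e-06), and so did Ltbp2, to 79.6 ± 3.29 (0.30, adjusted p = 0.00202). Lox fell from 1294 ± 66.7 to 518 ± 36.7 (-1.32, adjusted p = 1.02e-09), Col11a1 from 244 ± 2.74 to 106 ± 5.95 (-1.20) and Ccdc80 by 1.35. Postn rose from 754 ± 22 to 1783 ± 52.7 (1.24, adjusted p = 6.95e-11), Col5a1 by 1.04 and Col6a3 by 1.67. Wnt5a fell from 5.81 ± 0.632 to 2.61 ± 0.265 (-0.91, adjusted p = 3.3e-07). Itga5 (1.23), Tgfb2 (0.93), Nox4 (1.07) and Plat (1.56) rose and Vcl fell (-0.44). Contractile genes as a list had 14 of 31 higher and 8 lower (14 and 9 adjusted over the list alone; adjusted p = 0.149). Collagens had 10 of 18 higher and 4 lower (adjusted p = 0.0789), and matrix proteins 18 of 34 higher and 10 lower (19 and 11 adjusted over the list alone; adjusted p = 0.0598). YAP-TEAD targets had 11 of 23 higher and 8 lower (median 0.07, mean -0.02, adjusted p = 0.401).

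Of the 32 mitosis genes, 24 rose and 0 fell on knockdown under angiotensin II (median 0.49, adjusted p = 7.98e-06, or adjusted p = 0.469 with an estimated correlation), and 16 of 30 S phase genes rose and 1, Rrm1 (-0.59), fell (median 0.25, adjusted p = 0.000495, or adjusted p = 0.469 with an estimated correlation). Top2a reached 2.52 ± 0.737 FPKM (0.90, adjusted p = 5.2e-05), against 16.9 ± 2.98 in si-NC, and Cdk1 and Mcm5 rose by 0.77 and 0.73. Interferon-response genes rose in 22 of 32 and fell in 1 (median 0.72, adjusted p = 0.000155, or adjusted p = 0.494 with an estimated correlation), including Oasl2 (4 ± 0.448 to 11.9 ± 2.22 FPKM; 1.35, adjusted p = 0.00013) and Ddx58 (0.83). Cytokine genes rose in 10 of 19 and fell in 4 (median 0.20, adjusted p = 0.0334, or adjusted p = 0.469 with an estimated correlation, but 0.0612 after median-of-ratios scaling), with Cxcl12 (1.05) and Lif (0.86) up and Cx3cl1 down (-1.28). Fibroblast identity genes rose in 10 of 19 and fell in 5 (10 and 6 adjusted over the list alone; median 0.37, adjusted p = 0.021, or adjusted p = 0.469 with an estimated correlation). Thy1 went from 5.19 ± 0.707 to 24.4 ± 0.969 FPKM (2.05, adjusted p = 2.22e-11) and Dpt from 84.2 ± 14.2 to 365 ± 64.5 (2.10, adjusted p = 4.81e-10).

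Of 24 unfolded protein response genes, 11 fell and 3 rose with the knockdown under angiotensin II (median -0.10, adjusted p = 0.0367, or adjusted p = 0.469 with an estimated correlation, but 0.0612 after median-of-ratios scaling and 0.0588 after quantile normalization), with Atf4 at -0.42, Asns at -0.76 and Trib3 at -1.06. Cardiomyocyte genes fell in 15 of 21 and rose in 0 (median -0.28, adjusted p = 0.000324, or adjusted p = 0.469 with an estimated correlation), including Mybpc3 (238 ± 9.05 to 133 ± 3.96 FPKM). All 7 list calls of this comparison were lost with an estimated correlation.

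**Figure D4:**
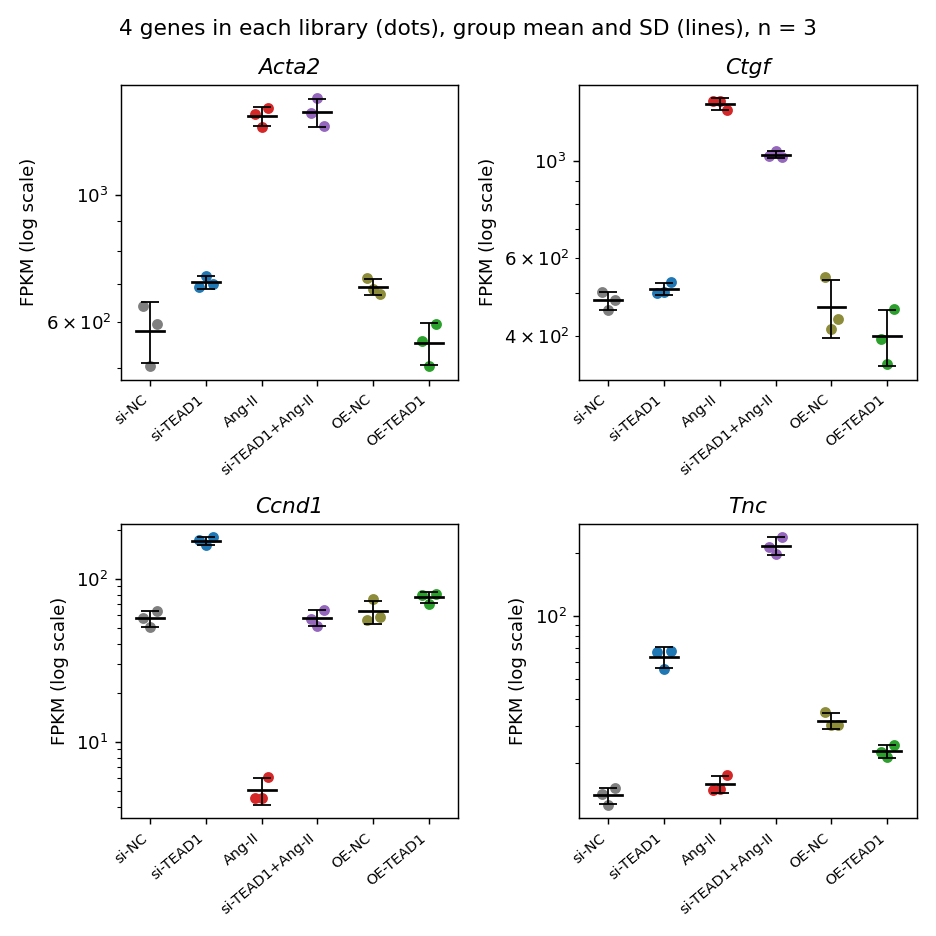
FPKM on a log axis of Acta2, Ctgf, Ccnd1 and Tnc in the 6 groups, with a dot per library and a black line at the mean. Acta2 averaged 1372 with Ang-II and 1396 with si-TEAD1+Ang-II, while Ccnd1 went from 5.05 to 57.7.

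The interaction asked whether angiotensin II changed the size of the knockdown effect, measured as the knockdown difference with the stimulus minus that without it. A small part of the genes tested had a knockdown effect that differed detectably with angiotensin II. Tnc, Ccnd1 and Ngf rose more when the stimulus was present. Col15a1, Mtnr1a, Ptx3 and Wnt5a had lower differences with it.

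The test called 694 genes, 289 with a higher and 405 with a lower knockdown effect under angiotensin II, and 29 differed at least 2-fold. Voom on the recovered reads called 650, of which 531 were shared. The differences were 1.57 for Tnc (SE 0.13, adjusted p = 4.06e-06), 1.71 for Ccnd1 (SE 0.16, adjusted p = 1.33e-05) and 1.57 for Ngf (SE 0.16, adjusted p = 2.33e-05). Plat (0.99, adjusted p = 5.17e-05) and Dpt (0.81, adjusted p = 0.0105) also had higher differences. Lower ones included Col15a1 (-1.65, adjusted p = 1.33e-05), Mtnr1a (-1.41, adjusted p = 8.93e-05), Ptx3 (-0.97, adjusted p = 9.47e-05) and Wnt5a (-0.66, adjusted p = 0.00549). Cyr61 (-0.37, adjusted p = 0.0121) and Col1a1 (-0.27, adjusted p = 0.0146) differed in the same direction. The difference for Ctgf was -0.47 (adjusted p = 0.034). It stayed at -0.49 to -0.44 but lost its call (adjusted p up to 0.08) when any of the 12 libraries was left out except Ang-II replicate 3 or si-NC replicate 1. The gene with the most negative value, Saa3 (-4.68, adjusted p = 0.0411), and the most positive, Retnla (2.72, adjusted p = 0.0494), each lost its call without any of several libraries, up to adjusted p = 0.106 without si-NC replicate 3 and 0.132 without Ang-II replicate 1.

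Mitosis genes had the strongest list result of the interaction, but it depended on the scale. On log2(FPKM + 1), 19 of 32 had a lower knockdown effect with angiotensin II (28 adjusted over the list alone; median -0.73, adjusted p = 7.35e-23, or adjusted p = 0.402 with an estimated correlation). With a pseudocount of 0.1 in place of 1 this was 5 of 32 (median -0.27, adjusted p = 6.54e-05), and with voom 1 of 32 (median -0.18). In Ang-II cells these genes lay near or below 1 FPKM, where the pseudocount of 1 shrinks a ratio. S phase genes, with 0 higher and 1 lower of 30 (median -0.18, adjusted p = 0.00649, or adjusted p = 0.673 with an estimated correlation), were not called with the pseudocount of 0.1 (adjusted p = 0.336). Lists called on both of these scales were interferon response (0 higher and 3 lower of 32, 0 and 4 adjusted over the list alone; median -0.53, adjusted p = 1.86e-07, or adjusted p = 0.622 with an estimated correlation), unfolded protein response (0 and 4 of 24, 0 and 9; median -0.14, adjusted p = 1.08e-06, or adjusted p = 0.402 with an estimated correlation) and cholesterol synthesis (0 and 3 of 23, 0 and 4; median -0.20, adjusted p = 2.06e-06, or adjusted p = 0.622 with an estimated correlation). So were fibroblast identity (6 higher and 2 lower of 19, 9 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.000229, or adjusted p = 0.402 with an estimated correlation), p53 targets (1 and 4 of 20; median -0.14, adjusted p = 0.000654, or adjusted p = 0.582 with an estimated correlation), cardiomyocyte genes (0 and 3 of 21, 0 and 5; median -0.11, adjusted p = 0.00621, or adjusted p = 0.622 with an estimated correlation) and collagens (1 and 2 of 18, 1 and 6; median -0.08, adjusted p = 0.00847, or adjusted p = 0.582 with an estimated correlation). With an estimated correlation no list of the interaction was called, and the adjusted p of these 9 lists ran from 0.402 to 0.673.

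Overexpression of TEAD1, compared with OE-NC, asked which transcripts follow a raised TEAD1 level. Most of the cholesterol synthesis and matrix protein genes tested rose, and most NRF2-target and S phase genes fell. These lists also set OE-NC apart from si-NC, in the opposite direction: in OE-NC cholesterol genes were lower in 20 of 23, matrix proteins lower in 24 of 34, NRF2 targets higher in 14 of 16 and S phase genes higher in 29 of 30. Each was called there with an adjusted p of 7.84e-06 or lower, and none with an estimated correlation (adjusted p from 0.0959 to 0.257). The Wnt receptor, collagen, protease, TGF-beta, fibroblast identity, respiratory chain and glycolysis lists were also called in OE-NC against si-NC. Each went opposite to its call with OE-TEAD1, so rises and falls in these lists were toward the si-NC side. Immediate early and cardiomyocyte genes were not called between the controls. Tcf21 and Pdgfrb, members of the fibroblast identity list, rose, and Myc fell.

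The comparison called 6595 genes, 2894 higher and 3701 lower, of which 54 rose and 90 fell at least 2-fold. The surplus of lower calls depended on scaling, with 3215 higher and 3289 lower after median-of-ratios scaling and 3423 and 3235 after quantile normalization. Cholesterol synthesis genes rose in 22 of 23 and fell in 0 (median 1.03, adjusted p = 9.64e-19, or adjusted p = 0.209 with an estimated correlation). Ldlr rose from 41.3 ± 2.12 to 107 ± 4.28 FPKM (1.35, SE 0.05, adjusted p = 3.8e-12), against 102 in si-NC, Hmgcs1 from 57.4 ± 4.63 to 137 ± 6.39 (1.24) and Mvk from 16 ± 2.22 to 48.5 ± 4.77 (1.54). Heg1 rose from 26.9 ± 1.33 to 81.9 ± 7.47 (1.57, adjusted p = 9.04e-12), Cemip from 34.5 ± 11.4 to 132 ± 24.1 (1.93, adjusted p = 4.84e-07) and Mgp from 61.5 ± 22.5 to 161 ± 21.6 (1.44, adjusted p = 1.11e-05). Saa3, low in OE-NC at 0.483 ± 0.308, rose to 34.3 ± 13.8 (4.51, SE 0.92, adjusted p = 0.000481). Slc2a6 and Mvd were also among the 10 largest rises (1.72 and 1.42), as was Ccl5 (1.36, adjusted p = 0.0281), whose call was lost with a pseudocount of 0.1 (adjusted p = 0.0616), without the low-value filter (0.0578) and when any of 5 libraries was left out (up to 0.069).

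Matrix proteins rose in 23 of 34 and fell in 6 (median 0.33, adjusted p = 3.88e-06, or adjusted p = 0.0897 with an estimated correlation), and collagens in 13 of 18 with 1 lower (13 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00018, or adjusted p = 0.215 with an estimated correlation). Col1a1 rose from 502 ± 12.6 to 661 ± 19.2 FPKM (0.40, adjusted p = 7.41e-07), Col5a1 and Col6a1 each by 0.48, Dcn from 242 ± 10.4 to 373 ± 18.8 (0.62) and Bgn from 1215 ± 35.3 to 1594 ± 13.7 (0.39). Matrix proteases and inhibitors rose in 12 of 22 and fell in 5 (median 0.23, adjusted p = 0.00903, or adjusted p = 0.0897 with an estimated correlation), led by Timp3 (100 ± 5.16 to 238 ± 25; 1.24) and Timp2 (0.78). Fibroblast identity genes rose in 12 of 19 and fell in 1 (median 0.40, adjusted p = 0.000159, or adjusted p = 0.215 with an estimated correlation), with Tcf21 up from 116 ± 6.8 to 217 ± 11.7 and Pdgfrb by 0.66. The si-NC means of Col1a1, Dcn and Tcf21, given above, were higher than their OE-NC means. Wnt receptors and modulators rose in 13 of 27 and fell in 1 (median 0.11, adjusted p = 0.0101, or adjusted p = 0.276 with an estimated correlation), among them Sfrp2 (0.94), Sfrp1 (0.65) and Dvl3 (0.45). TGF-beta signalling genes rose in 12 of 29 and fell in 8 (13 and 8 adjusted over the list alone; median 0.13, adjusted p = 0.0432, or adjusted p = 0.358 with an estimated correlation, but 0.0701 after quantile normalization), with Tgfb3 at 0.74, Tgfbr2 at 0.51 and Ski at 0.47.

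Hspa1a fell from 48.8 ± 10.1 to 2.7 ± 0.899 FPKM (-3.76, SE 0.20, adjusted p = 2.75e-10) and Hspa1b by 3.16. These near-identical genes share reads, so how the fall divides between them is uncertain. Procr, Ptgs2, Myh7, Fosl1, Crct1, Plaur, Crabp1 and Sema6a were the other largest falls (-2.51 to -1.68), and Myh7 went from 41.9 ± 4.97 to 8.63 ± 2.32. Hspa8, chosen after its values were seen, fell from 1827 ± 92.9 to 958 ± 51.7 (-0.93, adjusted p = 4.18e-11). NRF2 targets fell in 13 of 16 and rose in 1 (14 and 1 adjusted over the list alone; median -0.64, adjusted p = 7.27e-06, or adjusted p = 0.215 with an estimated correlation), with Hmox1 down from 251 ± 18.1 to 112 ± 10.3 (-1.16, adjusted p = 3.76e-10), Gclm by 1.34 and Slc7a11 by 1.49. S phase genes fell in 29 of 30 and rose in 0 (median -0.61, adjusted p = 6.73e-09, or adjusted p = 0.336 with an estimated correlation), including Mcm6 (46.4 ± 0.641 to 22.3 ± 2.51; -1.03) and Ccne2 (-1.20). Mitosis genes fell in 10 of 32 and rose in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.159). Immediate early genes fell in 12 of 22 and rose in 1 (median -0.28, adjusted p = 0.0125, or adjusted p = 0.358 with an estimated correlation), with Myc down from 36.1 ± 1.18 to 16.7 ± 1.23 (-1.07), Jun by 0.50 and Ier3 by 0.61.

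Respiratory chain genes fell in 23 of 30 and rose in 0 (24 and 0 adjusted over the list alone; median -0.20, adjusted p = 1.31e-05, or adjusted p = 0.215 with an estimated correlation), and glycolysis genes fell in 15 of 25 and rose in 4 (15 and 5; median -0.17, adjusted p = 0.0395, or adjusted p = 0.341 with an estimated correlation), including Hk2 (-0.84). Cardiomyocyte genes fell in 13 of 21 and rose in 2 (13 and 3 adjusted over the list alone; median -0.33, adjusted p = 0.0125, or adjusted p = 0.583 with an estimated correlation), with Nppa at 643 ± 41.5 FPKM against 1044 ± 21.2. The estimated correlation left none of these 13 lists called, with adjusted p from 0.0897 for matrix proteins and proteases to 0.583 for cardiomyocyte genes. Contractile genes had 8 of 31 higher and 13 lower (adjusted p = 0.439), with Fhl2 up (0.54) and Myl9 (-0.50) and Tpm1 (-0.32) down. YAP-TEAD targets had 9 of 23 higher and 10 lower (9 and 8 after median-of-ratios scaling; adjusted p = 0.635), Ankrd1 (-0.49) and Nt5e (-1.09) among the falls. BET proteins and P-TEFb had 0 of 11 higher and 4 lower (adjusted p = 0.159). Interferon genes had 0 of 32 higher and 10 lower (adjusted p = 0.158). Isg15, also chosen after its values were seen, was 111 ± 10.9 in OE-NC and 78.3 ± 44.6 in OE-TEAD1 (-0.66, adjusted p = 0.0833), and was called without OE-TEAD1 replicate 3 (-1.08, adjusted p = 0.00345) or with voom (-0.68, adjusted p = 0.023).

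The OE-NC and si-NC controls were compared to see how far levels can be set side by side between the arms. They differed in more genes than any treated group did from its control. Most of the interferon, NRF2-target and S phase genes tested were higher in OE-NC, and most of the cholesterol and matrix protein genes were lower. OE-TEAD1 lay nearer to si-NC than OE-NC did.

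The controls differed in 8259 genes, 4716 higher and 3543 lower in OE-NC, and 453 rises and 226 falls were at least 2-fold. The surplus of higher calls depended on scaling, with 4166 higher and 4064 lower after median-of-ratios scaling and 4032 and 4271 after quantile normalization. The root mean square difference over genes was 0.51 log2 units between OE-NC and si-NC, 0.334 between OE-NC and OE-TEAD1, and 0.257 between OE-TEAD1 and si-NC. Examples chosen after their values were seen are Hspa1a (1.53 FPKM in si-NC, 48.8 in OE-NC; 4.30, adjusted p = 7.54e-12), Isg15 (9.64 ± 0.895 and 111 ± 10.9; 3.39, adjusted p = 3.33e-08), Hmox1 (81.3 and 251; 1.61, adjusted p = 1.17e-12) and Ldlr (102 and 41.3; -1.28, adjusted p = 4.36e-13). Of 14 lists called, interferon genes were higher in 31 of 32 (32 adjusted over the list alone; median 1.66, adjusted p = 8.99e-09, or adjusted p = 0.401 with an estimated correlation) and S phase genes in 29 of 30 (median 1.01, adjusted p = 1.43e-09, or adjusted p = 0.257 with an estimated correlation). Cholesterol genes were lower in 20 of 23 (median -0.78, adjusted p = 1.43e-09, or adjusted p = 0.257 with an estimated correlation). NRF2 targets were higher in 14 of 16 and lower in 1 (median 1.15, adjusted p = 7.84e-06, or adjusted p = 0.23 with an estimated correlation), and respiratory chain genes were higher in 29 of 30 and lower in 0 (29 and 1 adjusted over the list alone; median 0.33, adjusted p = 6.42e-07, or adjusted p = 0.22 with an estimated correlation). Mitosis genes were higher in 28 of 32 (median 0.54, adjusted p = 0.00227, or adjusted p = 0.728 with an estimated correlation) and glycolysis genes in 18 of 25, with 4 lower (median 0.38, adjusted p = 0.00955, or adjusted p = 0.257 with an estimated correlation). Matrix proteins were lower in 24 of 34 and higher in 6 (median -0.54, adjusted p = 6.42e-07, or adjusted p = 0.0959 with an estimated correlation), collagens lower in 13 of 18 and higher in 1 (median -0.26, adjusted p = 0.0016, or adjusted p = 0.257 with an estimated correlation), and fibroblast identity genes lower in 13 of 19 and higher in 1 (median -0.57, adjusted p = 0.000125, or adjusted p = 0.23 with an estimated correlation). Wnt receptors (16 lower and 4 higher of 27, adjusted p = 0.00365, or adjusted p = 0.23 with an estimated correlation), Hippo genes (13 and 4 of 22, adjusted p = 0.0152, or adjusted p = 0.22 with an estimated correlation), TGF-beta genes (16 and 9 of 29, 17 and 10 adjusted over the list alone, adjusted p = 0.0223, or adjusted p = 0.302 with an estimated correlation) and proteases (13 and 6 of 22, adjusted p = 0.0397, or adjusted p = 0.22 with an estimated correlation) were lower. Protease genes lost this call after median-of-ratios scaling (adjusted p = 0.0601) and quantile normalization (adjusted p = 0.0984), and TGF-beta genes after quantile normalization (adjusted p = 0.0506). No call held with an estimated correlation, whose adjusted p ran from 0.0959 to 0.728.

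**Figure D5:**
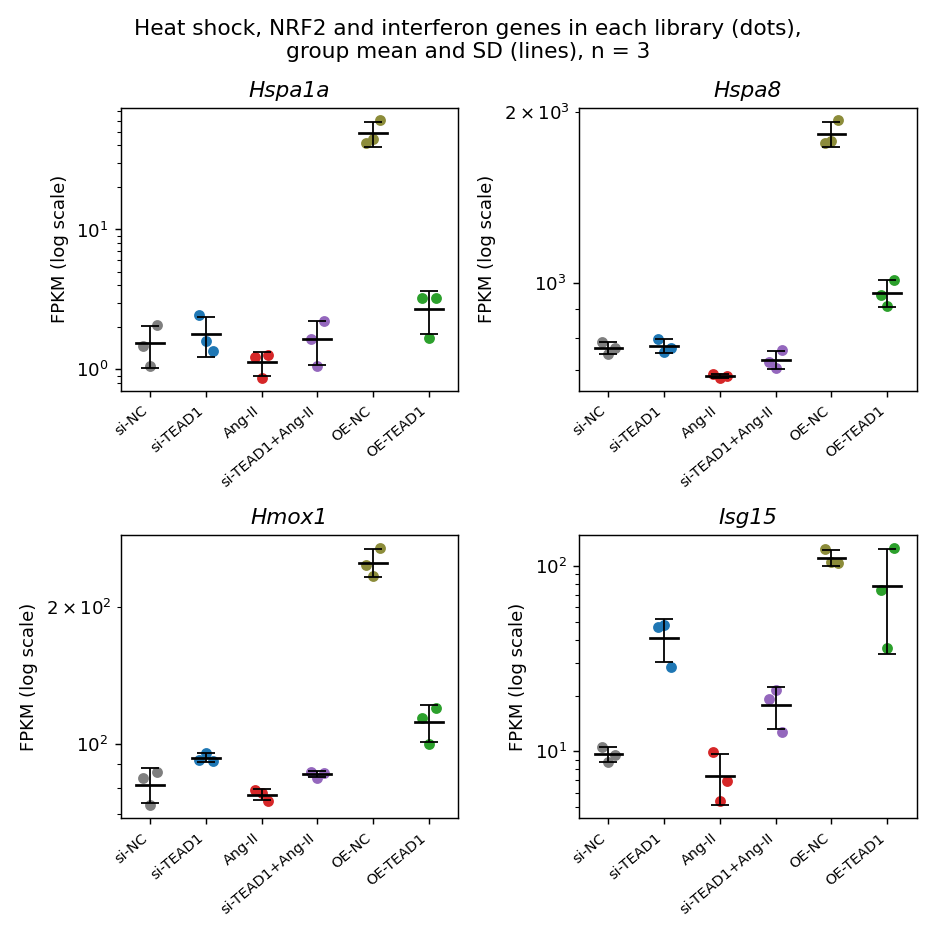
FPKM on a log axis of Hspa1a, Hspa8, Hmox1 and Isg15 in the 6 groups, with a dot per library and a black line at the mean. Hspa1a averaged 48.8 in OE-NC and between 1.12 and 2.7 in the other groups.

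Knockdown and overexpression were set against each other to see whether the same genes moved in opposite directions. They share no libraries. Across 11844 genes, which are not independent replicates, the fold changes had Pearson's r = -0.27 and Spearman's rho = -0.28. Of 3130 genes called in both, 70.4% went in opposite directions. Genes up with si-TEAD1 and down with OE-TEAD1 numbered 1085, against 761 for independent lists, and genes down and then up 1120 against 650. Genes up in both numbered 431 against 595, and down in both 494 against 832. Since OE-NC differed from si-NC as well, the correlation of the OE-TEAD1 effect with the OE-NC difference from si-NC was computed: r = -0.87 (rho = -0.89), where the shared OE-NC libraries alone gave a simulated -0.5 (SD 0.015), with a covariance of -0.1541 against a simulated -0.004. Of 5939 genes called in both, 99.2% were opposite, so OE-TEAD1 levels lay on the si-NC side of OE-NC for nearly all of them. The OE-NC difference from si-NC was also set against the knockdown effect: r = 0.41, where the shared si-NC libraries alone gave a simulated 0.5 (SD 0.015), with a covariance of 0.0688 against a simulated 0.004. With the si-NC libraries split 1 and 2 between the differences, r was 0.33 to 0.41 and the covariance 0.0587 to 0.0704 over the 6 ways. Of 3820 genes called in both, 1429 were up in both, against 970 for independent lists, 1377 down in both, against 796, and 26.5% opposite. The opposition of knockdown and overexpression is therefore not independent of how OE-NC differs from si-NC.

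The knockdown effects with and without angiotensin II, which also share no libraries, had r = 0.80 (rho = 0.77) across genes. Of 3508 genes called in both, 1605 rose in both, against 483 for independent lists, and 1849 fell in both, against 586, while 1.5% were opposite. To ask whether knockdown ran against the angiotensin II change, the Ang-II effect was correlated with the knockdown effect in stimulated cells. The value was r = -0.23 (rho = -0.18), less negative than the -0.5 (SD 0.018) that the shared Ang-II libraries alone give with no effects. The covariance was -0.0305 against a simulated -0.004, a difference of -0.0265. Of 2770 genes called in both, 58.2% were opposite: 510 went up and then down, against 291 for independent lists, and 1101 went down and then up, against 870. Genes up in both numbered 333, also above the 261 for independent lists, and genes down in both 826 against 966. With the 3 Ang-II libraries split 1 and 2, so that no library was in both differences, the covariance was -0.0215 to -0.0305 over the 6 ways (mean -0.027) and r was -0.22 to -0.15. The Ang-II effect and the knockdown effect in unstimulated cells had r = -0.17 (rho = -0.05), where sharing si-NC acts toward a positive value. Their covariance was -0.0214 against a simulated 0.004. Of 2997 genes called in both, 50% were opposite. Counts exceeded those of independent lists in the same direction (407 up and 1092 down, against 271 and 986). They did so in opposite directions too (376 and 1122, against 296 and 902). The Ang-II and OE-TEAD1 effects were uncorrelated (r = 0.01).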

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

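The knockdown effect of the genes in this part was called as different with angiotensin II by limma's test of the interaction. A positive value means a larger rise or a smaller fall on knockdown when angiotensin II was present. If the Ang-II cells did not receive the control siRNA, which the labels leave open, an effect of transfection cannot be told apart. In all, 694 genes were called. The checks of these genes with voom and the test of the interaction lists with a pseudocount of 0.1 were chosen after the result was seen. All groups held 3 libraries, too few for a test of single outlying libraries, and every column of the table was used.

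Among the higher values, the interaction was 1.71 for Ccnd1, 1.57 for Tnc, 1.57 for Ngf, 1.12 for Lrrn4, 1.06 for Hist1h4i, 1 for C1qtnf1, 0.99 for Plat, 0.81 for Dpt, 0.6 for Itga5 and 0.46 for Plk2. Less firm values were 2.72 for Retnla, 1.32 for Ptgs2, 1.17 for Clec3b, 1.15 for Gja4, 0.91 for Notch4, 0.54 for Gna14, 0.51 for Thy1, 0.48 for Msln, 0.33 for Fzd4, 0.26 for Col5a1 and 0.21 for Vim, each of which lost its call under an alternative or without a library.

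Among the lower values, the interaction was -0.27 for Col1a1, -0.28 for Atf4, -0.37 for Cyr61, -0.45 for Ccdc80, -0.66 for Wnt5a, -0.8 for Rrm1, -0.88 for Vnn1, -0.94 for Gdf15, -0.97 for Ptx3, -1.11 for Osr1, -1.11 for Trim59, -1.12 for Trim12a, -1.13 for Cenpa, -1.26 for Fam83d, -1.41 for Mtnr1a and -1.65 for Col15a1. Values that lost their call under an alternative or without a library were -0.26 for Myl2, -0.41 for Adamts9, -0.47 for Ctgf, -0.54 for Cx3cl1, -0.68 for Cdo1, -0.71 for Trib3, -0.78 for Hmmr, -0.89 for Cdc20, -1 for Cenpe, -1.05 for Ect2, -1.06 for Cenpf and -4.68 for Saa3. Of these 49 genes, 37 were called in the same direction by voom and 38 with a pseudocount of 0.1. The mitosis genes Hmmr, Cdc20, Cenpe and Cenpf, near or below 1 FPKM with Ang-II, were not called by voom: Cenpf had -0.39 (adjusted p = 0.698).

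Other splits of the same 12 libraries gave no measure of chance for these counts. Of 100 regroupings drawn, the real one included, 6 called as many genes as the real 694, and the highest other called 5316, several times the real number. For the 9 gene lists called, 40 of the 100 called as many, and the highest other called 16. These numbers point to the structure of the samples: a regrouping carries the effects of knockdown and of angiotensin II themselves into the contrast, so this test is void.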

How the results depend on the processing

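Counts of called genes and the size of the Tead1 change held under most alternatives, and the gene list calls did not. Voom on the recovered reads, the other scalings of lists, the thinned libraries, the split of shared control libraries and the interaction lists with a pseudocount of 0.1 were chosen after seeing the data.

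Requiring a 2-fold change left 232 genes with si-TEAD1, 417 with Ang-II, 259 with si-TEAD1+Ang-II, 144 with OE-TEAD1, 29 in the interaction and 679 for OE-NC against si-NC, because few called genes changed that much. Under the other alternatives each count stayed within 1.5 times the reported one. Voom shared 5008 of 5096 calls in the same direction with si-TEAD1, 5604 of 5706 with Ang-II, 4794 of 4957 with si-TEAD1+Ang-II, 6311 of 6595 with OE-TEAD1 and 531 of 694 in the interaction, with 0 opposite.

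Leaving out single replicates gave 4300 to 4640 genes with si-TEAD1, 4993 to 5200 with Ang-II, 4272 to 4512 with si-TEAD1+Ang-II, 5827 to 6307 with OE-TEAD1, 474 to 659 in the interaction and 7807 to 7947 for OE-NC against si-NC. Tead1 ran from -1.47 to -1.37 with si-TEAD1, -1.63 to -1.53 with si-TEAD1+Ang-II and 1.49 to 1.71 with OE-TEAD1, called each time. The small Ang-II value of Tead1 ran from 0.18 to 0.23 and lost its call in each of these, with fewer samples. It also lost it at 0.21 without the low-value filter (adjusted p = 0.079), without the trend (0.0603) and with the replicate block (0.052). Other settings made it larger or firmer: 0.33 (adjusted p = 0.00357) with median-of-ratios scaling, 0.34 (0.000912) with voom on such library sizes, 0.26 (0.0166) with quantile normalization, 0.21 (0.0226) with voom and 0.21 (0.00164) with the compared groups alone. The cause was not tested.

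With an estimated correlation the number of lists called was 0 with si-TEAD1, 1 with Ang-II, 0 with si-TEAD1+Ang-II, 0 with OE-TEAD1, 0 in the interaction and 0 for OE-NC against si-NC. The cause was not tested. Calls were lost for lists with an estimate below the preset value too, such as pericyte genes with Ang-II (adjusted p = 0.0225 and 0.12) and matrix proteases with OE-TEAD1 (0.00903 and 0.0897).

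The correlation of knockdown and overexpression effects ran from -0.32 to -0.2 over the leave-outs, lowest in size without OE-TEAD1 replicate 2. That of the Ang-II effect with knockdown in stimulated cells ran from -0.26 to -0.2, and was -0.29 with a pseudocount of 0.1, -0.19 after quantile normalization, and -0.33 with voom and with voom on median-of-ratios library sizes. The cause was not tested.

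Among named genes, values near 0 changed sign. Brd4 in si-TEAD1+Ang-II against Ang-II became -0.03, 0 and -0.02 without Ang-II replicate 1, si-TEAD1+Ang-II replicate 1 and si-TEAD1+Ang-II replicate 3. The interaction of Wnt4 became 0.04, 0.01 and 0.01 without Ang-II replicate 2, si-TEAD1+Ang-II replicate 1 and si-NC replicate 3. Acta2 in si-TEAD1+Ang-II became -0.11 after quantile normalization and -0.01 and -0.02 without Ang-II replicate 2 and si-TEAD1+Ang-II replicate 2. None of these was called, and the cause was not tested. Over all leave-outs Brd4 ran from -0.03 to 0.08, Wnt4 from -0.16 to 0.04 and Acta2 from -0.02 to 0.06. Over all 337 named results and their 5696 values under alternatives, 5500 kept direction and side of the threshold, 182 lost a call, 5 gained one and 9 changed sign. These involved 36 results.

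Replicate numbers are shared between groups, but the labels do not say that they pair samples. Deviations of same-numbered samples had correlations of -0.06 to 0.29, mostly positive. Most samples, though not all, were closest to their own number, so a shared replicate effect stays open. The main fit took them to share only a number. With the replicate block the interaction called 963 genes against 694, and every other count rose too. These were 5407 against 5096 with si-TEAD1, 6050 against 5706 with Ang-II and 5289 against 4957 with si-TEAD1+Ang-II. OE-TEAD1 gave 6910 against 6595, and OE-NC with si-NC 8472 against 8259. The block added 1 list call with si-TEAD1 (11 against 10), 2 with si-TEAD1+Ang-II (9 against 7) and 1 in the interaction (10 against 9). It took away that of TGF-beta genes with OE-TEAD1 (adjusted p = 0.0551).

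Depth limits the rare transcripts: Wnt4 rested on 21 to 238 reads per library, and genes below 1 FPKM have fold changes set largely by the pseudocount.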

Other observations

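Genes that fell on knockdown in both the absence and the presence of angiotensin II often rose on overexpression. Of 1849 genes lower in both knockdown comparisons, 825 (44.6%) were higher with OE-TEAD1, against 24.4% of all genes, and 363 (19.6%) were lower, against 31.2%. The guanylate cyclase gene Gucy1a3 had log2 fold changes of -1.33, -1.32 and 1.28 in the 3 comparisons, the potassium channel gene Kcne4 -1.93, -2.07 and 0.96, and Gas1 -1.44, -1.43 and 0.92. Scg2 (-2.07, -2.33 and 1.13), Upk3b (-1.58, -1.7 and 1.09) and Wisp2 (-1.17, -0.92 and 1.27) followed the same order. Of 1605 genes higher in both knockdown comparisons, 666 (41.5%) were lower with OE-TEAD1, against 31.2% of all genes, and 332 (20.7%) were higher, against 24.4%. Among them were Fosl1 (1.46, 1.79 and -2.08), Nes (1.8, 2.05 and -1.02), Sprr1a (2.2, 2.54 and -1.02), Plaur (0.91, 1.4 and -1.74), Plk2 (0.95, 1.41 and -0.99) and Ptx3 (2.44, 1.47 and -0.83). This 3-way comparison and its examples were chosen after the values were seen, and OE-NC differed from si-NC in most of the genes tested.

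The splits of libraries, the depth test and the tests of the most-read genes were set out before their results were seen; the other tests of explanations were chosen after the pattern they address had been seen.

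Heat shock genes, in a list written after their values were seen, were lower in OE-TEAD1 than in OE-NC in 14 of 16 (median -0.73, SE 0.33), and higher in OE-NC than in si-NC in 14. The SE of a list median, here and below, is taken over its genes. These are not independent, and it does not measure the spread between libraries. With all libraries thinned to the smallest total the median was -0.74. FPKM is scaled to library size, so thinning would leave this median in place, and the test cannot decide on the lower depth of OE-NC. A dose effect of TEAD1 that also runs below the control level is argued against by the median of 0.08 with si-TEAD1. Handling of the OE-NC cultures remains open, because OE-TEAD1 was 0.26 above si-NC while OE-NC was 0.83 above it, and the design holds no further control. An effect of raised TEAD1 alone, in one direction, stays open as well.

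Interferon-response genes were higher with si-TEAD1 (median 1). A larger share of macrophages among the cells is argued against by the macrophage markers, of which 0 were higher and 4 lower of 19. Their median was -0.02 (SE 0.05 over genes) and Lyz2 was at 361 against 427 FPKM, though this says nothing of a stronger response in the macrophages present. Tead1 level as the sole influence across both arms is argued against by OE-TEAD1, where Tead1 was higher than in si-NC and the interferon genes lay 1.5 above it. An effect of Tead1 beside a difference between the arms stays open: OE-NC lay 1.66 above si-NC, and within the overexpression arm OE-TEAD1 had a median of -0.29 against OE-NC (0 higher and 10 lower of 32), without a list call (adjusted p = 0.158). Of all genes tested, 24.4% were higher and 31.2% lower with OE-TEAD1, so the count lower among interferon genes was near the general share. A response to the siRNA duplex and one to the loss of Tead1 cannot be told apart: the genes were also higher with si-TEAD1+Ang-II than with Ang-II (median 0.72), and a single siRNA label covers both groups.

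Most calls with Ang-II were lower than si-NC, 23.1% being higher. A first test by median-of-ratios scaling was dropped, because that scaling centres the genes by construction. Leaving the 10 most-read genes out of the library totals gave 25.8%, which argues against their larger share as the cause. Leaving out the 100 most-read genes, which took 19.98% of reads in si-NC and 22.91% in Ang-II, gave 33.2%, so their share may account for part of the imbalance, and it cannot be told apart from a true fall of many genes. No biological explanation was tested.

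Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 with as many genes called with si-TEAD1 (5096, highest other 0), Ang-II (5706, highest other 1), si-TEAD1+Ang-II (4957, highest other 0), OE-TEAD1 (6595, highest other 0) and OE-NC against si-NC (8259, highest other 0). For gene lists, 4 of the 10 splits called as many as the real 10 with si-TEAD1 (highest other 14), 1 as many as the real 16 with Ang-II (13), 6 as many as the real 7 with si-TEAD1+Ang-II (14), 2 as many as the real 13 with OE-TEAD1 (16) and 3 as many as the real 14 with OE-NC (15). Every other split mixes both groups and keeps part of their real difference. These splits therefore give no measure of chance for the counts of genes or lists. For the correlation of knockdown and overexpression effects, 29 of 100 joint splits gave a size as large as the real 0.27 (highest other 0.46). For that of the Ang-II effect with knockdown in stimulated cells, 77 of 100 regroupings gave a value at least as far below 0 as the real 0.23 (highest other 0.94). Both tests of correlations are void as well. Each joint split keeps part of the real difference with either sign, and each regrouping shares a middle group, which alone gives a correlation of -0.5.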
